A study of Solanum lycopersicum with 15 samples.

How the data were processed

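Tomato roots were sampled under 5 nutrient regimes with 3 libraries each. Per the labels' protocols, total RNA was extracted from about 60 mg of ground root powder with a plant RNA kit, and libraries of polyadenylated RNA were made from 2 µg of total RNA with an mRNA sequencing kit. The values analysed were FPKM per gene as deposited by the authors, a unit read from the file headers, in a single table of 34075 genes by 15 libraries. Reads were aligned with HISAT2, per the submitters' processing notes. The version of the aligner, the genome build and the tool that computed FPKM were not given in the sources used here, and the identifiers carry the annotation name ITAG4.0. Each column was assigned to a library by its name, and each library to its regime by its sample label. The values of 0 pairs of libraries were identical.

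FPKM divides by transcript length and by the mapped fragments of a library, so it corrects for depth but not for differences in the composition of the RNA, and an abundant transcript that rises lowers the values of all others. Count-based tests do not apply to such values. The FPKM sums ranged from 546848 to 589451 and the 10 most expressed genes held 3.88% to 4.97% of them. Median-of-ratios size factors lay between 0.941 and 1.07, with a mean of 0.956 ± 0.014 for urea and 1.037 ± 0.057 for iron alone (SD, n = 3). Relative depth was estimated from the steps between the low values of genes present in few libraries. All 105 pairs of libraries gave ratios that matched a single depth per library within 0.05 on the log2 scale, and the method recovered simulated depths with a largest error of 0.001. The absolute depth stays unknown, so no counting interval can be given. An exact 0 can be a failed estimate. In 91 genes, 86 of them tested, a library was listed at 0 while the other 2 of its regime were at 5 FPKM or more, at 4 to 14 genes per library. Of these, 0 were called for iron and at most 3 in any comparison. For named genes with such values the value of each library is given.

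Genes with at least 1 FPKM in at least 3 libraries were kept, which left 18889 genes (55.4%). Another 9632 genes were at 0 in every library. Values were transformed as log2(FPKM + 1), so a log2 change is on that scale and understates the change of low genes. A linear model with a mean per regime was fitted to all 15 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a mean-variance trend), because 3 libraries per regime give few residual degrees of freedom. All p-values named adjusted are two-sided limma p-values with Benjamini-Hochberg adjustment within a comparison, and a gene was called, or said to have changed, at an adjusted p under 0.05. The 10 comparisons were iron alone against control, each nitrogen form against iron alone, the forms against each other, and each form against control. They, the filter and the alternatives were chosen before the data were examined. The model was tested on simulated data with the mean of each gene over all libraries and its fitted spread, drawn as independent normal values. It recovered 79%, 74%, 84% and 81% of genes changed 2-fold and 98%, 96%, 96% and 92% of those changed 4-fold for iron, nitrate, ammonium and urea, and false calls made up 0.56%, 1.73%, 4.26% and 4.42% of all calls, over 18889 genes. Low genes simulated to fall were first set to a higher level, so the recovery does not cover falls from low levels.

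Named genes were the 2 rising and the 2 falling genes per comparison with the largest change among those called, with a mean of at least 5 FPKM in 1 of the groups and groups that did not overlap. The rule written before the data were examined took more genes and asked for a product description. It was shortened because the file pairs no identifier with a name or product and the annotation table at hand (assembly SLM_r2.1) matched 0 of the identifiers. For the same reason 30 gene lists fixed beforehand, among them iron uptake, nitrate transport and ammonium assimilation, could not be matched, and none of their tests was run. Chromosomes are those in the identifiers, and no coordinates are given because no annotation of the same build was used here.

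Overlaps between comparisons that share libraries were set beside the overlap of independent lists, and the log2 changes of these comparisons beside 20 simulations of unchanged groups. The simulations gave all regimes the same spread per gene. Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, size factors, quantile normalization, no variance trend, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. Scaling all libraries to equal FPKM totals, and the alternatives for the genes that still differed from control with all 3 forms, were added after the data had been seen.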

Results

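Polyadenylated RNA was sequenced from tomato (Solanum lycopersicum) roots under 5 nutrient regimes, with 3 libraries per regime and 15 in all. Control roots had neither iron nor nitrogen. The remaining roots were given iron back, either alone or together with nitrate, ammonium or urea, which sets the response to iron beside what each nitrogen form adds to it. Expression was available as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 34075 genes, and 18889 of them were expressed highly enough to be tested. The FPKM values of a library summed to between 546848 and 589451, and between 17357 and 18082 genes reached 1 FPKM. Read counts were not part of the values, so the absolute depth is unknown, but the steps between low values put the depth of the libraries at 0.87 to 1.28 relative to each other. The labels do not say whether the replicates came from separate plants or cultures. The p-values set each difference against the spread between libraries of a regime, estimated over all 5 regimes. That spread may be technical. Genes are given by identifier, because the file pairs none of them with a name.

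Roots of the 5 regimes separated in the principal components of log2(FPKM + 1). The first component, with 25.5% of the variance, ran from control roots at -36.1 to -29.8 to roots given iron and urea at 37.3 to 53.6, with iron and ammonium at 12.4 to 19.5. The second component, with 16.5%, set roots given nitrate apart at -41.5 to -25.7. Roots given iron alone were lowest on the third component at -42.4 to -13, and their replicate 3 lay nearest to the control roots on the first. Libraries of one regime correlated at 0.96 to 0.975 across genes, and iron alone held the lowest of these values. Genes are not independent replicates, and these correlations only describe how alike the libraries were.

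**Figure D1:**
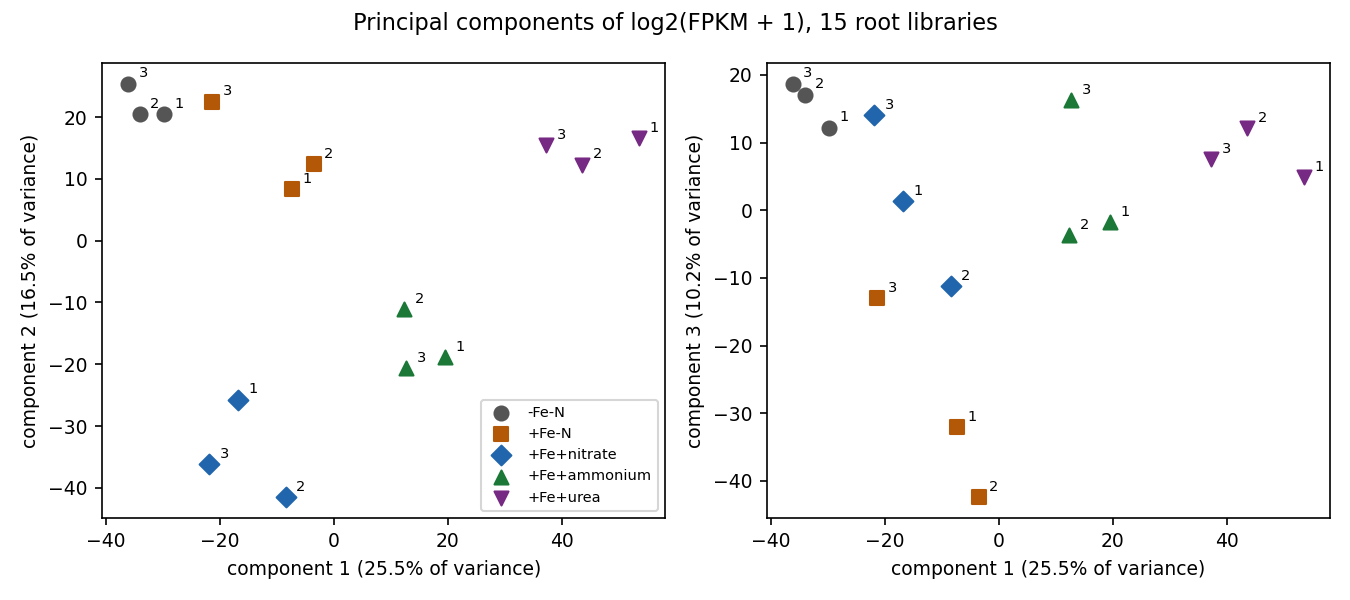
Scores of the 15 root libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2(FPKM + 1) over the tested genes. Each point is a library, numbered by replicate and coloured by regime; component 1 (25.5% of the variance) places control roots at -36.1 to -29.8 and roots given iron and urea at 37.3 to 53.6.

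Roots given iron alone were compared with control roots, both without nitrogen. The largest rise among the genes named by the rule was that of Solyc01g104820.ITAG4.0 on chromosome 1, from 5.83 ± 1.49 to 191 ± 59.6 FPKM (SD, n = 3), a log2 change of 4.79 with a standard error of 0.23 (adjusted p = 3.4e-07). Solyc12g088970.1.ITAG4.0 on chromosome 12 rose from 8.2 ± 8.04 to 94.9 ± 60.3 FPKM (n = 3; log2 change 3.79, standard error 0.84, adjusted p = 0.018). In the falling direction Solyc03g026280.3.ITAG4.0 went from 27.6 ± 11 to 3.0 ± 3.73 FPKM (n = 3; log2 change -3.15, standard error 0.74, adjusted p = 0.024). Its neighbour by identifier, Solyc03g026270.3.ITAG4.0, stood at 12.5, 23.6 and 8.64 FPKM in control roots and was listed at 0, 0 and 0.784 FPKM with iron (adjusted p = 0.00014). In all, 1209 genes changed, 6.4% of those tested, of which 561 rose and 648 fell, and 133 rose and 181 fell by at least 2-fold. The genes that rose were expressed at a median of 26.5 FPKM over all libraries and those that fell at 18.2 FPKM, against 9.48 FPKM for all tested genes. Called genes lay above that level in every comparison, at medians of 13.5 to 31.5 FPKM, so this was not particular to iron.

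With all libraries scaled to equal FPKM totals the split for iron moved to 426 rising and 903 falling genes. Without iron-alone replicate 1 it was 209 rising and 332 falling, and without replicate 2, where it turned round, 304 and 285. Without control replicate 1, 2 and 3 it was 319 and 428, 241 and 306, and 223 and 307, so which direction was the more frequent depends on a single library. The count depended on single libraries and on the shared estimate of spread: it was 747, 547 and 530 without control replicate 1, 2 and 3, 541 and 589 without iron-alone replicate 1 and 2, and 708 when only these groups were fitted. Over single libraries left out, the genes rising by at least 2-fold numbered 77 to 176 and those falling 105 to 306. The call of Solyc12g088970.1.ITAG4.0 was lost with only these groups (adjusted p = 0.094) and without iron-alone replicate 1 or 2 (0.081 and 0.066), over a range of 0.012 to 0.094 in 15 alternatives, and that of Solyc03g026280.3.ITAG4.0 was lost with a pseudocount of 0.1 (adjusted p = 0.096) and without control replicate 2 or 3 (0.084 and 0.089) or iron-alone replicate 1 or 2 (0.1 and 0.085), over a range of 0.0022 to 0.1.

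**Figure D2:**
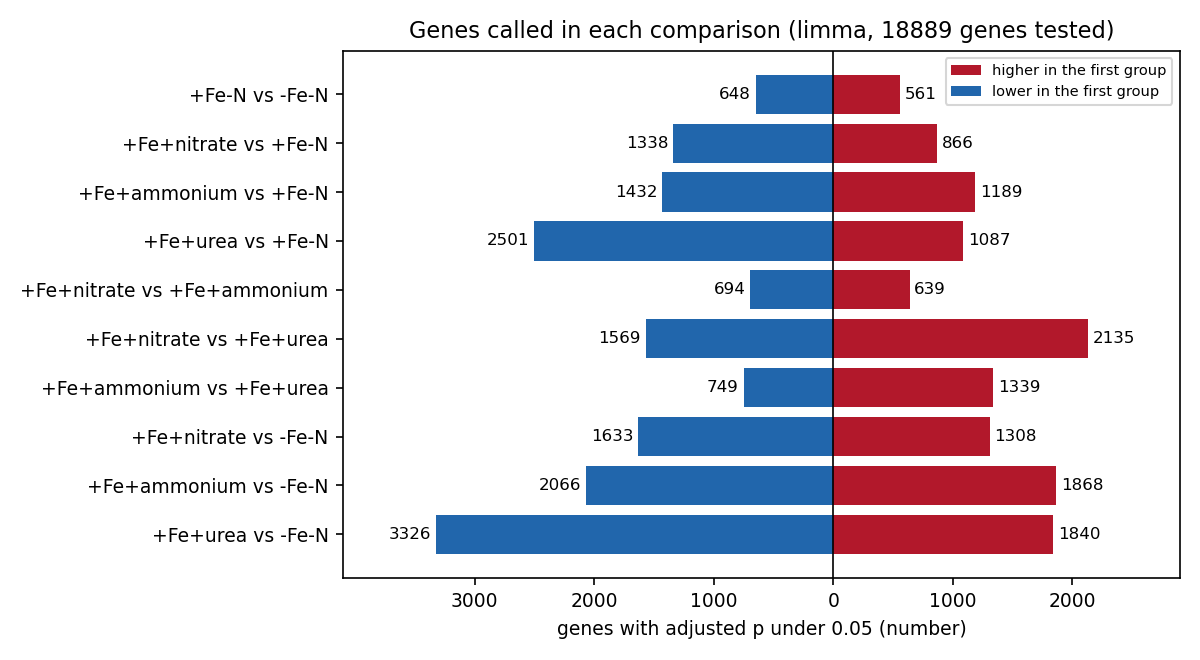
Number of genes with an adjusted p under 0.05 in each of the 10 comparisons (horizontal axis, genes), with genes higher in the first-named regime to the right and genes lower in it to the left. Counts are for FPKM as deposited; the balance between the directions changes with the scaling of the libraries, for urea against iron alone from 1087 rising and 2501 falling to 1777 and 1589 with size factors.

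Nitrate was compared with iron alone to see what it adds. Solyc03g119180.1.ITAG4.0 on chromosome 3 rose from 3.8 ± 1.97 to 111 ± 18.6 FPKM (n = 3; log2 change 4.64, standard error 0.71, adjusted p = 0.00095), and Solyc08g007430.ITAG4.0 on chromosome 8 from 1.77 ± 0.929 to 44 ± 19.8 FPKM (n = 3; log2 change 3.96, standard error 0.45, adjusted p = 7.9e-05). Solyc03g091020.1.ITAG4.0, at 19.8 ± 2.88 FPKM with iron alone (n = 3), fell to listed values of 1.53, 0 and 0.72 FPKM with nitrate (adjusted p = 0.00082). Solyc01g056320.1.ITAG4.0 on chromosome 1 stood at 23.4, 35.1 and 67.2 FPKM with iron alone and was listed at 0 in all 3 nitrate libraries (adjusted p = 0.013). It was also listed at 0 in 2 of the 3 control libraries and 2 of the 3 urea libraries, and did not differ by the test between nitrate and control (adjusted p = 0.58). Nitrate changed 2204 genes, 11.7% of those tested, with 268 rising and 221 falling by at least 2-fold.

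As deposited, 866 of the genes called for nitrate rose and 1338 fell, and with equal FPKM totals 992 rose and 1255 fell. With size factors, which centre the median gene by construction, the split was 1125 rising and 1061 falling. The data therefore do not fix which direction was the more frequent. The count was 1221 without nitrate replicate 3 and 1192 when only these groups were fitted, and 144 genes fell by at least 2-fold without nitrate replicate 3. Without iron-alone replicate 1 the split was 776 rising and 875 falling, and without nitrate replicate 3 it was 543 and 678.

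Ammonium, also compared with iron alone, raised Solyc05g009320.ITAG4.0 on chromosome 5 from 17.4 ± 2.48 to 249 ± 26.3 FPKM (n = 3; log2 change 3.77, standard error 0.14, adjusted p = 1.4e-08). It raised Solyc04g077990.ITAG4.0 on chromosome 4 from 1.27 ± 1.36 to 26.3 ± 4.18 FPKM (n = 3; log2 change 3.76, standard error 0.38, adjusted p = 4.7e-05). Both were also higher with urea than with iron alone, at 147 ± 7.88 and 8.64 ± 1.79 FPKM (n = 3; adjusted p = 1.2e-07 and 0.001), while with nitrate they stood at 23.5 ± 3.63 and 0.39 ± 0.26 FPKM (n = 3; adjusted p = 0.08 and 0.41). Solyc01g056320.1.ITAG4.0 was listed at 0 in every ammonium library (adjusted p = 0.011), as in every nitrate library. Solyc01g014860.ITAG4.0, at 28.9, 14.6 and 74.1 FPKM with iron alone, was likewise listed at 0 in the 3 ammonium libraries (adjusted p = 0.022). It was also listed at 0 in most other libraries outside iron alone, at 9.53, 0 and 0 FPKM in control roots, 10.5, 0 and 0 with nitrate and 0, 0 and 26.1 with urea, and ammonium did not differ from these by the test (adjusted p = 0.6, 0.7 and 0.48). Altogether 2621 genes changed with ammonium, 13.9% of those tested, with 169 rising and 228 falling by at least 2-fold.

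Of the genes called for ammonium, 1189 rose and 1432 fell as deposited, and 1268 rose and 1489 fell with equal FPKM totals. With size factors, which centre the median gene by construction, 1459 rose and 1248 fell, so the more frequent direction depends on the scaling. The count was 1616 and 1672 without ammonium replicate 1 and 3, and 1318 when only these groups were fitted. Without iron-alone replicate 1 the split was 1060 rising and 982 falling, and without replicate 2 it was 751 and 1193. Without ammonium replicate 1 and 3 it was 687 and 929, and 813 and 859. The call of Solyc01g014860.ITAG4.0 was lost without iron-alone replicate 1 or 3 (adjusted p = 0.051 and 0.076) and without ammonium replicate 1 or 3 (0.062 and 0.06), over a range of 0.0045 to 0.076.

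Urea gave the largest individual increases over iron alone. Solyc06g050870.ITAG4.0 on chromosome 6 rose from 4.96 ± 5.21 to 460 ± 121 FPKM (n = 3; log2 change 6.59, standard error 0.50, adjusted p = 2.5e-06). Solyc10g050990.ITAG4.0 on chromosome 10 stood at 430, 535 and 300 FPKM with urea, against values listed at 0, 0 and 4.87 FPKM with iron alone (adjusted p = 4.3e-05), and at 19.1, 3.0 and 29.5 FPKM with ammonium. Solyc03g119590.1.ITAG4.0 fell from 17.4 ± 3.92 to 2.18 ± 1.59 FPKM (n = 3; log2 change -2.63, standard error 0.47, adjusted p = 0.0016). Solyc09g011490.ITAG4.0 on chromosome 9 fell from 19.4 ± 2.45 to 2.47 ± 1.03 FPKM with urea (n = 3; log2 change -2.59, standard error 0.23, adjusted p = 7.9e-06). It also fell with nitrate and ammonium, with log2 changes of -1.63 and -2.14 (adjusted p = 0.00046 and 8.1e-05). Urea changed 3588 genes, 19.0% of those tested, and 316 rose and 406 fell by at least 2-fold. Of the genes it raised, 10 went from a mean under 1 FPKM to at least 10 FPKM, whereas limma called 0 such genes for nitrate and 0 for ammonium (2 and 1 at an unadjusted p under 0.05). In the other direction, from at least 10 FPKM to under 1 FPKM, it called 0 genes for urea, 2 for nitrate and 3 for ammonium.

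Among the genes called for urea, 1087 rose and 2501 fell as deposited, 1777 rose and 1589 fell with size factors, and 1534 rose and 1719 fell after quantile normalization. Size factors set the median gene to no change, which was a log2 change of -0.095 as deposited, so the split is not settled by these data. When only these groups were fitted the count was 2317, and with a pseudocount of 0.1 the genes falling by at least 2-fold numbered 635. Without urea replicate 1, 1644 genes fell.

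**Figure D3:**
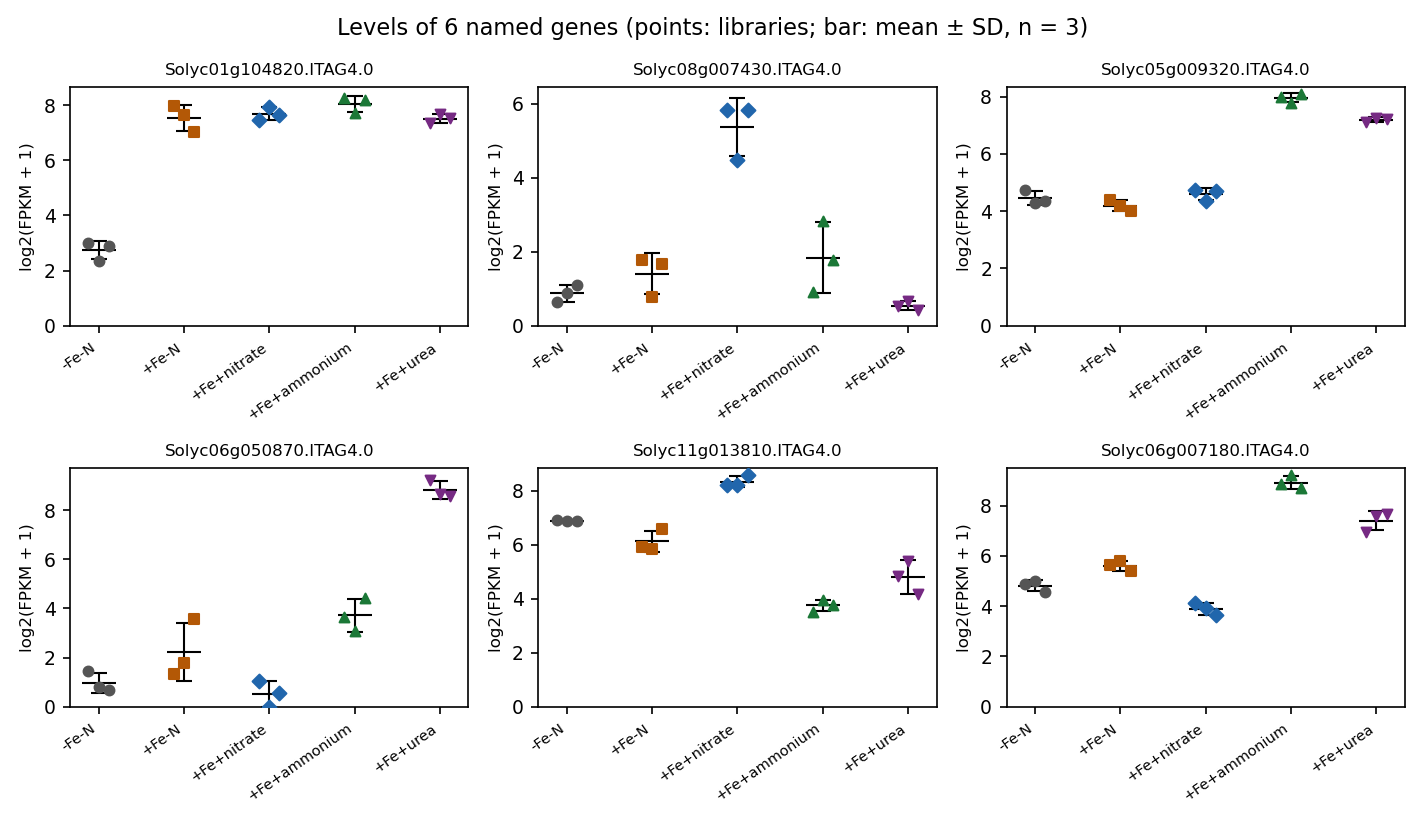
Expression of 6 of the named genes in the 5 regimes on the log2(FPKM + 1) scale, with a point per library and bars for the mean and SD of 3 libraries. Solyc01g104820.ITAG4.0 was high in every regime with iron, Solyc08g007430.ITAG4.0 with nitrate, Solyc05g009320.ITAG4.0 with ammonium and urea, Solyc06g050870.ITAG4.0 with urea, and Solyc11g013810.ITAG4.0 and Solyc06g007180.ITAG4.0 moved in opposite directions with nitrate and ammonium.

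The calls for the nitrogen forms against iron alone overlapped in part. Of 5625 genes called for at least 1 form against iron alone, 599 were called in the same direction for all 3, 182 rising and 417 falling, and this split became 341 rising and 288 falling with size factors and 289 and 331 after quantile normalization. Another 3482 genes were called for 1 form only, of which 806 were called for nitrate, 816 for ammonium and 1860 for urea, which does not show that they responded differently to the others. Ammonium and urea had 1358 genes called in the same direction (414 rising and 944 falling), nitrate and ammonium 1021 (449 and 572), and nitrate and urea 808 (211 and 597).

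Independent lists of these sizes would share 68.4 rising and 189.6 falling genes for ammonium and urea, 54.5 and 101.4 for nitrate and ammonium, and 49.8 and 177.2 for nitrate and urea. The log2 changes across genes correlated at 0.58, 0.56 and 0.26 for these pairs, against 0.5 for unchanged groups simulated against the same iron-alone libraries. Their covariances were 0.122, 0.106 and 0.0571, exceeding the simulated 0.0265, 0.026 and 0.0262 by 0.0952, 0.0804 and 0.0309. The 3 iron-alone libraries are too few to split, and a shift common to them would give the same overlap and excess covariance. Part or all of the excess may therefore come from the shared iron-alone libraries. A response shared by the forms cannot be told apart from such a shift. When each form was fitted with only the iron-alone libraries, 251 genes were called in the same direction for all 3, and 700, 430 and 383 for these pairs. Without nitrate replicate 3 the pairs with nitrate shared 670 and 509.

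Direct comparison of nitrate with ammonium tested the difference between these forms. Solyc11g013810.ITAG4.0 on chromosome 11 reached 326 ± 48.5 FPKM with nitrate and 12.6 ± 2.07 with ammonium (n = 3; log2 difference 4.59, standard error 0.26, adjusted p = 4.1e-07), on either side of its 70.8 ± 21.2 FPKM with iron alone. Solyc06g074710.1.ITAG4.0 on chromosome 6 stood at 25 ± 2.58 and 0.77 ± 0.0252 FPKM (n = 3; log2 difference 3.87, standard error 0.30, adjusted p = 5.9e-06). Conversely Solyc06g007180.ITAG4.0 was at 14.0 ± 2.58 FPKM with nitrate and 487 ± 88.7 with ammonium (n = 3; log2 difference -5.02, standard error 0.20, adjusted p = 2.1e-08), and Solyc04g077990.ITAG4.0 at 0.39 ± 0.26 and 26.3 ± 4.18 FPKM (n = 3; log2 difference -4.30, standard error 0.38, adjusted p = 1.3e-05). In this comparison 1333 genes differed, 7.06% of those tested, with 210 higher and 168 lower by at least 2-fold with nitrate.

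Of these, 639 were higher and 694 lower with nitrate as deposited, and 710 and 646 with size factors, which turns the small imbalance round. The count was 840 without ammonium replicate 1, with 393 lower with nitrate, and 791 when only these groups were fitted.

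Nitrate and urea differed in 3704 genes, 19.6% of those tested, with 502 higher and 452 lower by at least 2-fold with nitrate. Solyc01g108630.ITAG4.0 on chromosome 1 stood at 136 ± 19.3 FPKM with nitrate and 1.91 ± 1.01 with urea (n = 3; log2 difference 5.60, standard error 0.30, adjusted p = 6.6e-08). Solyc03g119180.1.ITAG4.0 was at 90.1, 118 and 126 FPKM with nitrate and listed at 8.0, 0 and 0 FPKM with urea (adjusted p = 7.5e-05). Solyc06g050870.ITAG4.0 was listed at 1.06, 0 and 0.458 FPKM with nitrate, against 600, 397 and 384 FPKM with urea (adjusted p = 1.3e-07). Solyc10g050990.ITAG4.0 was listed at 0 in all 3 nitrate libraries and stood at 300 FPKM or more in each urea library (adjusted p = 1e-05). As deposited 2135 genes were higher and 1569 lower with nitrate, and with size factors 1750 were higher and 1972 lower. Without urea replicate 1, 1411 were higher.

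Ammonium and urea differed in 2088 genes, 11.1% of those tested, with 144 higher and 255 lower by at least 2-fold with ammonium. Solyc02g089140.ITAG4.0 on chromosome 2 was at 0.574 ± 0.0412 FPKM with ammonium and 59.5 ± 17.5 with urea (n = 3; log2 difference -5.22, standard error 0.31, adjusted p = 2.1e-06). Solyc04g010140.1.ITAG4.0 was listed at 0 in every ammonium, nitrate and iron-alone library at 14, 0 and 0 FPKM in control roots and at 24.9, 89.2 and 38.3 FPKM with urea (adjusted p = 0.00068 against ammonium). Solyc01g108630.ITAG4.0 was higher with ammonium, at 14.0 ± 4.77 against 1.91 ± 1.01 FPKM (n = 3; log2 difference 2.37, standard error 0.30, adjusted p = 0.00029). Solyc03g115985.1.ITAG4.0 was at 4.61, 5.46 and 7.3 FPKM with ammonium and listed at 0 in the 3 urea libraries (adjusted p = 0.015).

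As deposited 1339 of these genes were higher and 749 lower with ammonium, with size factors 827 and 1049, and after quantile normalization 981 and 872. The count was 1220 without ammonium replicate 1, 948 without urea replicate 1 and 900 when only these groups were fitted, 229 genes were at least 2-fold higher with ammonium at a pseudocount of 0.1, and the call of Solyc03g115985.1.ITAG4.0 was lost without ammonium replicate 3 or urea replicate 1 (adjusted p = 0.052 and 0.055), over a range of 0.0035 to 0.055. Genes higher with ammonium numbered 707 and 851 without ammonium replicate 1 and 3, and without urea replicate 1 556 were higher and 392 lower.

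Genes were counted as specific to a form when called against iron alone and, in the same direction, against both other forms. The other forms need not have left them unchanged. Solyc05g009320.ITAG4.0 counts for ammonium although urea also raised it over iron alone (log2 change 3.01, adjusted p = 1.2e-07). Nitrate had 485 such genes, of which 268 rose and 217 fell, and 158 rose and 57 fell by at least 2-fold. Ammonium had 105, with 75 rising and 30 falling as deposited and 60 and 43 with size factors, and 28 rose and 9 fell by at least 2-fold. Urea had 895, with 407 rising and 488 falling as deposited, but 564 and 260 with size factors and 481 and 316 after quantile normalization, so that the more frequent direction turns with the scaling, and 223 rose and 111 fell by at least 2-fold. This direction also turns with single libraries left out, to 257 and 192 without urea replicate 1, 347 and 292, 352 and 349, and 369 and 348 without ammonium replicate 1, 2 and 3, and 392 and 383, and 384 and 381 without iron-alone replicate 1 and 3, and to 262 and 130 with only the groups of each comparison. The count for nitrate was 278 without nitrate replicate 3, with 103 falling, that for ammonium 57 and 69 without ammonium replicate 1 and 3, and that for urea 449 without urea replicate 1. When only the groups of each comparison were fitted, the counts were 277, 47 and 392 for nitrate, ammonium and urea.

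Genes that changed with iron alone were followed into the roots that also had nitrogen. A gene was counted as changed back when its change with nitrogen was called in the direction opposite to iron, wherever it then stood against control. Of the 1209, nitrate changed 414 back (34.2%) and 61 further in the direction of iron. Ammonium changed 334 back (27.6%) and 105 further, and urea 295 back (24.4%) and 135 further. Some passed the control level, but how many was not counted. Solyc01g108630.ITAG4.0 fell with iron and stood above control with nitrate (log2 change 2.81, adjusted p = 4.6e-05). For nitrate, 239 of the genes changed back had risen with iron and 175 had fallen. Against control roots, 126 of the 561 genes that rose with iron were still higher with all 3 forms, and 263 of the 648 that fell were still lower. With size factors these were 147 and 277, with only the groups of each comparison 44 and 168, and without the variance trend 72 and 219. Without iron-alone replicate 1 they were 47 and 144, without replicate 2 87 and 150, and without control replicate 1, 2 and 3 66 and 204, 50 and 133, and 51 and 153. Iron alone and each form were set against the same control libraries, so some agreement would arise without a lasting effect of iron. How much was not estimated for these counts. Solyc01g104820.ITAG4.0 stayed at 207 ± 34.5, 267 ± 51.9 and 183 ± 20 FPKM with nitrate, ammonium and urea (n = 3), and none of these differed from iron alone by the test (adjusted p = 0.73, 0.17 and 0.96).

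Independent lists would give 69.4, 83.3 and 112 genes changed back for nitrate, ammonium and urea, and 71.6, 84.4 and 118 changed further. The iron-alone libraries enter both comparisons with opposite signs, which lists of calls cannot separate from an effect, so the log2 changes were compared with those of unchanged groups simulated against these libraries. Their covariances across genes were -0.0669, -0.0472 and -0.0317, against simulated means of -0.026, -0.0262 and -0.0261 and lowest values of -0.0296, -0.0293 and -0.0302 in 20 draws with expression kept at 0 or above. In 20 other draws without that limit the lowest were -0.0332, -0.0344 and -0.035, so the simulations leave urea open, and for nitrate and ammonium part of the covariance may come from these shared libraries. Both sets of draws gave every regime the same spread per gene, although iron alone had the widest, so simulated covariances may be too weak. Without control replicate 1, 2 and 3 the genes changed back numbered 269, 214 and 190 with nitrate, 202, 176 and 157 with ammonium, and 168, 148 and 120 with urea. Without iron-alone replicate 1 and 2 they numbered 217 and 178 with nitrate, 180 and 143 with ammonium, and 146 and 138 with urea. They were 265 without nitrate replicate 3, and 209 and 222 without ammonium replicate 1 and 3. When only the groups of each comparison were fitted they were 182, 168 and 158 for nitrate, ammonium and urea. The genes changed further moved too, to 21, 39 and 54 without iron-alone replicate 2, 25, 46 and 56 without replicate 1, and 24, 50 and 76 with only the groups compared. Over single libraries left out they ranged from 21 to 56 with nitrate, 39 to 91 with ammonium and 54 to 136 with urea.

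**Figure D4:**
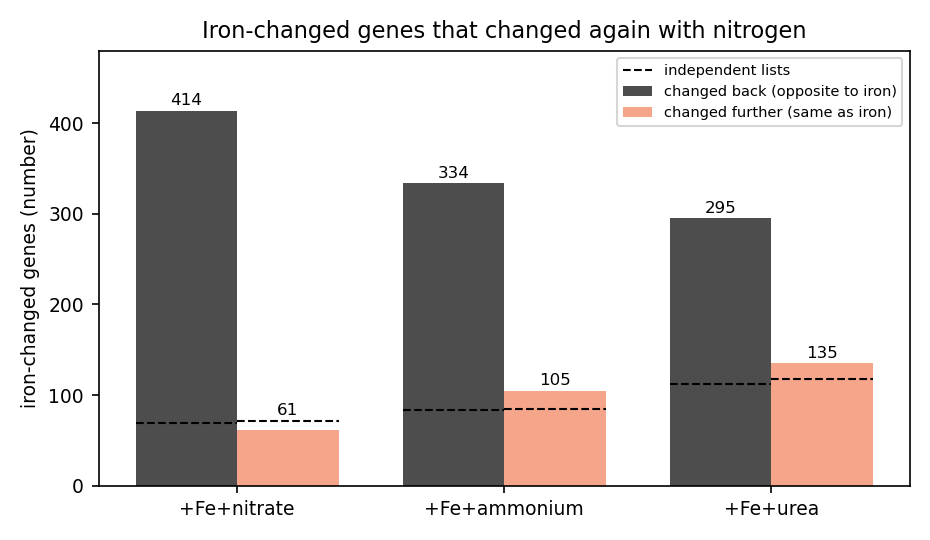
Number of genes changed by iron alone (vertical axis, out of 1209) that changed again when nitrate, ammonium or urea was added, in the direction opposite to iron (dark bars) or in the same direction (light bars). Dashed lines mark the overlap of independent lists; 414, 334 and 295 genes changed back with nitrate, ammonium and urea.

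Against control roots, iron and nitrogen changed together, and the number of changed genes was 2941 with nitrate, 3934 with ammonium and 5166 with urea, or 15.6%, 20.8% and 27.3% of those tested. Solyc01g104820.ITAG4.0 was higher than in control roots by log2 changes of 4.94, 5.30 and 4.77 (standard error 0.23; adjusted p = 8.4e-08, 3.1e-08 and 1.2e-07). Solyc12g017240.ITAG4.0 fell from 34.1 ± 18.5 FPKM to 2.88 ± 0.723, 1.1 ± 1.19 and 1.85 ± 0.728 FPKM (n = 3; adjusted p = 0.00062, 6.8e-05 and 0.00012). It already stood at 3.43 ± 2.95 FPKM with iron alone (n = 3; adjusted p = 0.0025 against control). None of the forms differed from iron alone by the test (adjusted p = 0.99, 0.17 and 0.53). Solyc03g093110.3.ITAG4.0 fell from 22.6 ± 12.3 to 2.67 ± 0.633, 0.503 ± 0.2 and 1.76 ± 0.621 FPKM (n = 3; adjusted p = 0.00018, 8.7e-06 and 3e-05). With iron alone it was already at 3.57 ± 1.63 FPKM (n = 3; adjusted p = 0.0019 against control), and it lay lower with ammonium than with iron alone (log2 change -1.55, standard error 0.33, adjusted p = 0.0079). Genes falling by at least 2-fold outnumbered those rising in each of these comparisons as deposited, at 393 against 248, 536 against 216 and 764 against 443.

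As deposited 1308 genes rose and 1633 fell with nitrate, 1868 and 2066 with ammonium, and 1840 and 3326 with urea. With size factors these splits were 1616 and 1490, 2103 and 2016, and 2673 and 2545. After quantile normalization they were 1602 and 1506, 2239 and 1918, and 2493 and 2573. Equal FPKM totals moved them the other way, to 1220 and 2075, 1591 and 2623, and 1727 and 3841. Without control replicate 3, 1080 genes fell with nitrate and 1368 with ammonium.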

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

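The tests of scaling and of depth for urea, of the shared iron-alone libraries and of chance placement were chosen only after the result was seen. Those of abundant genes, of a common shift and of shared reads, and the splits of the libraries, were written down before.

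Some genes moved in opposite directions with different nitrogen forms. Nitrate and urea had 175 such genes against iron alone, 95 rising with nitrate and falling with urea and 80 the reverse, nitrate and ammonium 39, and ammonium and urea 32. The direct difference was called in each of them, which follows almost from 2 called changes of opposite sign against the same libraries and is no separate evidence. The count for nitrate and urea was 108 and 92 without iron-alone replicate 1 and 3 and 107 without nitrate replicate 3, that for nitrate and ammonium 25 without iron-alone replicate 3 or nitrate replicate 3, and that for ammonium and urea 16, 18 and 14 without iron-alone replicate 1, 2 and 3, 21 and 16 without ammonium replicate 1 and 3, and 18 without urea replicate 1. When only the groups of each comparison were fitted, the counts were 90, 20 and 9. Solyc06g007180.ITAG4.0 fell with nitrate and rose with ammonium and urea, with nitrate minus ammonium at -5.02 and nitrate minus urea at -3.50 on the log2 scale. Solyc11g013810.ITAG4.0 did the reverse, at 4.59 and 3.53. Solyc06g074710.1.ITAG4.0 differed by 3.87 between nitrate and ammonium. Solyc06g050870.ITAG4.0 and Solyc01g108630.ITAG4.0 differed between nitrate and urea by -8.29 and 5.60. The fall of Solyc06g050870.ITAG4.0 with nitrate rested on low values (adjusted p = 0.044). They were 1.49, 2.43 and 11 FPKM with iron alone and 1.06, 0 and 0.458 FPKM with nitrate.

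Fewer genes rose than fell with urea, 30.3% of the calls as deposited. The relative depth argues against shallower urea libraries as the cause: it was 1.01 to 1.1 with urea and 1.28, 0.93 and 1.0 with iron alone, and 36.1% of the calls rose without iron-alone replicate 1, where every urea library was the deeper. The share of abundant genes argues against a few of them as the cause, because the share was 35.1% when the 100 most expressed genes were left out of the library totals. The scaling stays open: the share was 52.8% with size factors, which centre the median gene by construction, and 33.9% with equal FPKM totals. A shift of many genes with urea, which the design names, may equally lie behind it and cannot be told apart from the scaling here.

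Many genes changed by iron alone changed back, in the direction opposite to iron, when nitrogen was added. With equal spread in all regimes, the covariance of log2 changes argues against the shared iron-alone libraries as the whole cause for nitrate and ammonium. For nitrate it was -0.0669 against -0.0332 to -0.0252 in 20 simulations that let expression go below 0. For ammonium it was -0.0472 against -0.0344 to -0.0252. The simulations gave every regime the same spread per gene. Iron alone had the widest, with a median SD of 0.169 on the log2 scale against 0.134 to 0.159, so simulated covariances may be too weak. For urea the value of -0.0317 lay inside the simulated -0.035 to -0.0262, but beyond the lowest value of -0.0302 in 20 simulations that kept expression at 0 or above, and stays open. A shift common to the 3 iron-alone libraries and not due to iron stays open, since 134 of the 588 genes changed back by at least 1 form (22.8%) were changed back by all 3, and 83 of these were not called against control with any form. Partial cancelling of the iron response by nitrogen is a candidate explanation that the design cannot separate from such a shift. No regime had nitrogen without iron, so it also cannot be told whether the changes with nitrogen depend on iron.

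Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05, and the real split, which was 1 of 10 in each comparison, is given with the highest of the others. For iron, nitrate, ammonium and urea against their references these were 1209 and 0, 2204 and 3, 2621 and 1, and 3588 and 1 genes. For nitrate against ammonium, nitrate against urea and ammonium against urea they were 1333 and 1, 3704 and 2, and 2088 and 0, and for nitrate, ammonium and urea against control 2941 and 1, 3934 and 1, and 5166 and 1. The other splits mix the regimes, so any difference between the regimes widens the spread within their groups. Low counts in them follow from this and are no separate evidence on the grouping.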

How the results depend on the processing

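Scaling to equal FPKM totals, and the alternatives for genes still differing from control with all 3 forms, were chosen after the data had been seen, and the others before. Of the 171 recomputed counts of changed genes and of their overlap, 153 stayed within 1.5 times the value reported and 18 moved. Of the other counts, by direction, by 2-fold change, shared, changed back or further, still differing from control and specific to a form, 819 stayed within 1.5 times and 126 moved. Of 597 recomputed changes of named genes, 582 kept their call, 15 lost it and 0 changed direction. These genes were picked for large changes and groups that did not overlap. A reversal was therefore hardly possible, and its absence is no separate evidence. When only the groups compared were fitted, the counts were 708 for iron, 1192, 1318 and 2317 for nitrate, ammonium and urea against iron alone, 791 for nitrate against ammonium, 900 for ammonium against urea and 251 for the overlap of all 3 forms, with fewer libraries to estimate the spread. Leaving out 1 library at a time gave 530 to 1381 genes for iron, 1221 to 2076, 1616 to 2430 and 2409 to 3258 for nitrate, ammonium and urea against iron alone, 840 to 1109 for nitrate against ammonium, 2518 to 3206 for nitrate against urea and 948 to 1847 for ammonium against urea. Against control the ranges were 2013 to 2597, 2749 to 3440 and 3719 to 4383, and for the overlap 414 to 575. For iron the count was 747, 547 and 530 without control replicate 1, 2 and 3, and 541, 589 and 1381 without iron-alone replicate 1, 2 and 3. It was 1221 without nitrate replicate 3, 1616 and 1672 without ammonium replicate 1 and 3, 840 for nitrate against ammonium without ammonium replicate 1, and 1220 and 948 for ammonium against urea without ammonium replicate 1 and urea replicate 1. The cause was not tested beyond the smaller number of libraries. Solyc03g026280.3.ITAG4.0 also lost its call for nitrate against control with a pseudocount of 0.1 (adjusted p = 0.051, range 0.00041 to 0.051). No pairing of the libraries by replicate number was seen, which does not exclude it. Deviations of libraries with the same number correlated at -0.11 to 0.14 over 30 pairs (median 0.019). Those with different numbers correlated at -0.24 to 0.14 over 60 pairs (median -0.017). Of 15 libraries, 5 correlated best with their own number. With the replicate number as a block the counts were 1263, 2213, 2556 and 3535 for iron, nitrate, ammonium and urea, 1330, 3685 and 2012 between the forms, 2939, 3941 and 5155 against control, and 593 for the overlap. The list tests and their alternatives were not run, since no identifier could be matched to a list. Unknown absolute depth leaves the precision of low values open.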

Other observations

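The tests of neighbouring genes were chosen after the data had been seen, except that of shared reads, which was written down before its result.

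Tested genes next to each other by identifier, which follows the order along the 12 chromosomes, changed together more often than permuted calls. Neighbouring pairs were consecutive tested genes whose identifier numbers differed by at most 30, so untested genes can lie between them. With iron alone, 96 of 16876 neighbouring pairs changed in the same direction, 37 rising and 59 falling, in 74 runs, and 36 pairs changed in opposite directions. The 2 falling genes named for iron, Solyc03g026270.3.ITAG4.0 and Solyc03g026280.3.ITAG4.0, are such a pair. Nitrate against ammonium gave 115 same-direction pairs where 43.8 were drawn on average when calls were permuted among genes of like expression, a ratio of 2.63. The ratio was 2.66 for iron, 1.80, 1.56 and 1.43 for nitrate, ammonium and urea against iron alone, 1.73 for nitrate against urea and 1.56 for ammonium against urea.

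The permutations argue against chance placement of the iron pairs, since the highest of 1000 permutations gave 53 pairs against the 96 observed (permutation p = 0.001, one-sided, the smallest they can give; adjusted over 7 comparisons 0.001). Reads shared between near-identical neighbours stay open. Deviations of the paired genes within regimes correlated at a median of 0.41, against 0.15 for random same-direction pairs on other chromosomes with a 95th percentile of 0.23, as shared reads would give, but joint regulation of neighbours would give the same. Shared regulation of neighbouring genes, perhaps of gene families in tandem, is therefore a hypothesis that these values cannot separate from shared reads.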
